A study of Mus musculus with 37 samples.

How the data were processed

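RNA was measured in freshly sorted Tomato-positive cells of KPCT and KPC-colors mice, negative for CD45, CD31, F4/80 and Ter119 and for the dead-cell dye DAPI. Per the labels' protocols, RNA was extracted with a Qiagen micro kit, all samples had an RIN above 8, and libraries followed standard Illumina protocols. The deposited values are raw read counts, made by the authors with STAR 2.4.2a and HTSeq on mm10 per the submitters' processing notes. No normalisation was applied to them, and filters and the overlap mode of the counting are not stated. The table held 31469 rows of UCSC genes with 29640 distinct symbols and 35 columns of whole numbers. Even numbers made up 46.0 to 57.8% of counts from 1 to 20, depending on the library. The 2 technical replicates of the primary tumour and of the lymph node metastasis of mouse 0758 had been merged, per the labels. Gene positions were taken by symbol from GENCODE annotation of the same build and are protein-coding genes, except Mir147.

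Each column was put in its group and mouse by its own name. For 12 columns of mice 0784, 2542 and 2691 the sample descriptions point to another column of the same mouse, so that the fraction or site of these columns has conflicting labels and the mouse does not. The main fits follow the column name, and 2 alternatives leave these columns out or follow the descriptions. The designs, alternatives, gene lists and rule for naming genes were set before the data were examined. 3 alternatives were chosen after: the acinar list mean as a covariate, the any-metastasis fit without the lung library, and the relations in KPCT tumours alone.

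Comparisons used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust, TMM scaling, filterByExpr over the compared groups) with mouse as a block and Benjamini-Hochberg adjustment at 0.05. Log2 CPM used a prior count of 2. The GFP comparison used 12 libraries, and the metastasis comparisons 22, in 1 fit with a term for any metastasis and 1 fit with a term per site. In the fit by site, splenic, thoracic and lung metastases had 1 library each and were not tested. The peritoneal library was left out because its mouse had no whole-tumour library. The block follows from the labels, since the libraries of a pair come from 1 mouse. It was checked on the correlation of deviations from the group means, over the 1000 most variable genes. Same-mouse correlations were 0.59 to 0.81 for GFP pairs, 0.65 to 0.92 for primary tumour and lymph node, and 0.49 to 0.79 for primary tumour and liver, and the libraries correlated best with their own mouse in 6 of 6, 6 of 6 and 4 of 4 pairs. The splenic, thoracic, lung and peritoneal libraries were not part of this check. CPM by group come from the libraries of each fit, and CPM by library from 1 scaling over all 35.

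Gene lists were 17 programmes and 13 sets of cell type markers. Of their 536 distinct genes 511 were matched by symbol, 5 by an older name, and 20 had no row. Lists with at least 3 measured members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Alternatives were an estimated correlation and fry, which tests whether a set's genes move on balance one way without comparing them with other genes. Some genes stand in more than 1 list. The lists were written from general knowledge and not from these libraries. Markers of acinar, islet and duct cells belong to the tissue the tumours grew in, and Pdx1-cre also marks normal pancreas cells.

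The rule for named genes had 3 parts. Hmga2 and Prdm1 were always named. Up to 8 genes with the largest rise and 8 with the largest fall were named if past the threshold, with at least 3 mice in the comparison, a mean log2 CPM of at least 2 and the same sign in every pair, skipping gene models whose symbol gives no function. From each list the 4 members with the smallest p could be named. The report prints the members that illustrate a list. Some genes outside the rule are also named, mostly where single libraries or cell types are described, and not each is marked as such.

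The scripts were tested on simulated counts with 50 genes changed at each fold. Their spread was estimated with mouse alone, so real group differences counted as spread and the calls may be too few. For the GFP comparison 0 of 50 genes were called at 1.5-fold, 12 at 2-fold, 30 at 4-fold and 37 at 8-fold. The any-metastasis comparison called 6, 27, 43 and 46, the lymph node comparison 4, 13, 31 and 40, the liver comparison 0, 14, 30 and 42, and liver against lymph node 3, 9, 32 and 38. Between 2 and 4 unchanged genes were called in each. Duplicated libraries were looked for by the variance between columns of the same group relative to counting noise, and the lowest ratio was 38.9. Columns of different groups were not compared in this way. PCR reads are not independent molecules, so counting error is a lower bound on the noise of a count.

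Hmga2 by genotype was tested with an exact permutation test over all splits of the mice, and relations across tumours with exact permutation over pairings, adjusted over 3 relations. Alternatives for the gene comparisons were DESeq2 1.42.0, RLE size factors, no filter, a filter of 1 CPM in 50% of the libraries, no block, each mouse left out, and the treatments of conflicting columns. For any metastasis they were also the sum of counts per mouse and lymph node and liver metastases alone. No value column was left unused. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.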

Results

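RNA was sequenced from cancer cells sorted straight from pancreatic ductal adenocarcinomas (PDAC) and their metastases in 12 mice. In these mice Pdx1-cre, which is active in the pancreatic lineage, switched on mutant Kras, mutant p53 and the red reporter Tomato. The sorted cells were Tomato-positive and carried none of the surface markers of blood, endothelial and red cells used in the sort. KPC-colors mice had in addition a GFP reporter on 1 allele of Hmga2, a chromatin protein of fetal tissues, by which the cells were sorted as GFP-positive or GFP-negative. The 37 samples gave 35 libraries, since the 2 technical replicates of 2 samples from mouse 0758 were merged by the submitters. There were 6 GFP-negative and 6 GFP-positive libraries, 9 of whole primary tumours, 6 of lymph node metastases, 4 of liver metastases, and 1 each of splenic, thoracic, lung and peritoneal disseminated cells. Total counts per library ran from 34506180 to 63375319 in GFP-negative, from 35538026 to 72460265 in GFP-positive, from 41964294 to 67011852 in primary tumour, from 33986519 to 66620402 in lymph node metastasis and from 34192119 to 48724705 in liver metastasis libraries.

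The first question was how GFP-positive cells differ from GFP-negative cells of the same mouse. Genes of the hypoxia response and glycolysis were higher in GFP-positive cells in each of 6 mice. Of the 37 measured genes of that list, 34 rose and 3 did not pass the test, and 35 rose when adjusted over the list alone. The median log2 change was 1.83 (camera adjusted p = 5.94e-35, and adjusted p = 0.0113 with an estimated correlation). The list mean was higher by 1.73 to 2.15 log2 units in the 6 mice. Adm, the vasodilator peptide adrenomedullin (mm10 chromosome 7, 110627661 to 110629820), rose 18.8-fold, from 1.69 ± 1.34 to 32.9 ± 23.8 CPM (TMM-normalised read counts; SD, n = 6). Its log2 change was 4.23 (SE 0.35, edgeR adjusted p = 0.00172). The mitophagy gene Bnip3 (chromosome 7, 138890836 to 138909519) rose by 3.73 (SE 0.36, edgeR adjusted p = 0.00268), the lactate exporter Slc16a3 by 3.01 and the ankyrin repeat gene Ankrd37 by 3.13 log2 units. Egln3, an oxygen-sensing prolyl hydroxylase (chromosome 12, 54178981 to 54203860), went from 22.9 ± 14.7 to 174 ± 101 CPM, a log2 change of 3.02 (SE 0.13, edgeR adjusted p = 0.000203). Carbonic anhydrase Car9 (chromosome 4, 43506966 to 43513729) went from 16.5 ± 10.5 to 106 ± 60.8 CPM, and the glycolytic enzymes Pfkp and Pgk1 rose by 2.19 and 1.95. All of these genes were higher in 6 of 6 mice.

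Prdm1, which encodes the transcriptional repressor Blimp1 (chromosome 10, 44437177 to 44528501), rose from 4.14 ± 2.37 to 30.4 ± 14.7 CPM (SD, n = 6), a log2 change of 2.80 (SE 0.43, edgeR adjusted p = 0.0124). Hmga2 itself (chromosome 10, 120361275 to 120476469) stood at 237 ± 153 CPM in GFP-positive against 116 ± 77.5 in GFP-negative cells, a log2 change of 0.99 (SE 0.26, edgeR adjusted p = 0.055) that did not pass the test. Both genes were higher in 6 of 6 mice. Prdm1 did not pass without mouse 2542 (log2 2.72, adjusted p = 0.0512 in edgeR), and Hmga2 passed without mouse 0784 (1.18, adjusted p = 0.0249 in edgeR) and by DESeq2 (adjusted p = 0.00136). On a common scale for all 35 libraries, Hmga2 went from 112 to 121 CPM in mouse 0784, from 268 to 511 in 2317, from 59.0 to 74.1 in 2518, from 122 to 334 in 2542, from 108 to 277 in 2689 and from 41.4 to 158 in 2691. Prdm1 went in the same mice from 8.5 to 42.9, from 2.53 to 7.1, from 4.1 to 20.9, from 4.13 to 39.5, from 1.57 to 46.8 and from 4.27 to 30.4 CPM.

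**Figure D1:**
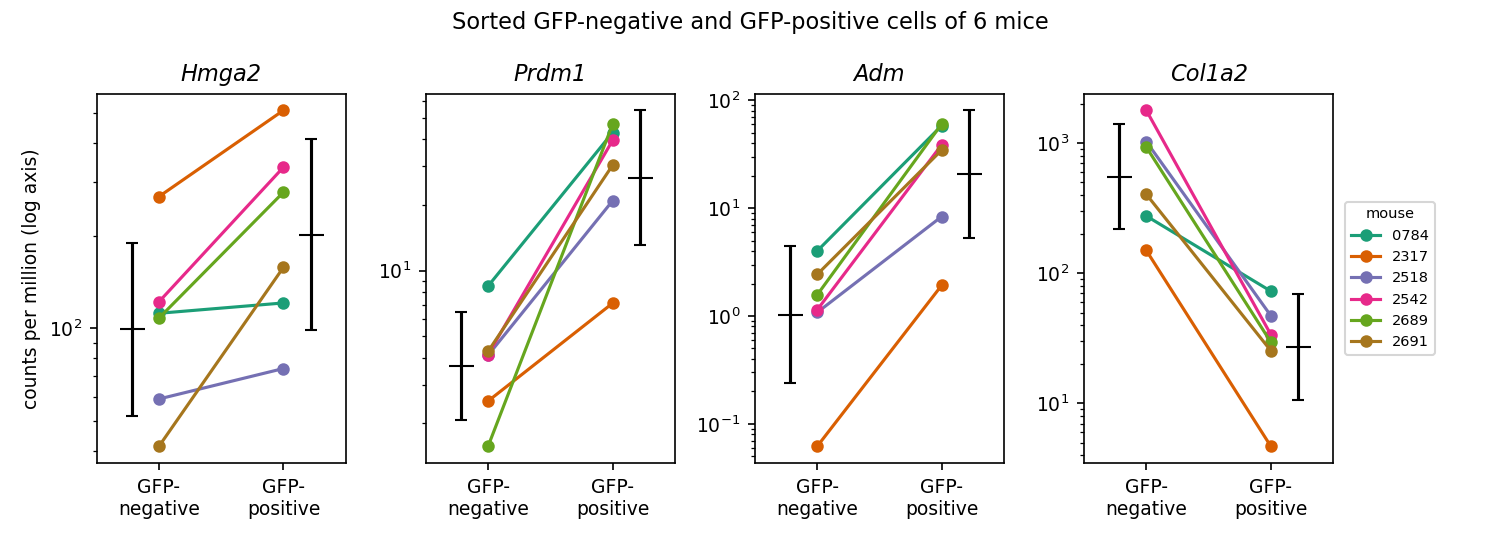
CPM (log axis) of Hmga2, Prdm1, Adm and Col1a2 in the GFP-negative and GFP-positive libraries of 6 mice, on a scale common to all 35 libraries; lines join the libraries of 1 mouse, and black bars are the mean and 1 SD of the log2 values. Hmga2, Prdm1 and Adm were higher and Col1a2 lower in the GFP-positive library of 6 of 6 mice.

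Genes of fibroblasts and acinar cells were lower in GFP-positive libraries. Of 13 fibroblast and pericyte markers 12 fell, with a median of −4.50 (camera adjusted p = 1.06e-12, and adjusted p = 0.329 with an estimated correlation), and the list mean was lower in 6 of 6 mice. Col1a2, a chain of collagen I, fell from 756 ± 615 to 34.4 ± 21.6 CPM and Col3a1 from 921 ± 806 to 38.5 ± 27.1. The matricellular gene Postn (chromosome 3, 54361109 to 54391037) fell by 5.35 on the log2 scale (SE 0.79, edgeR adjusted p = 0.0109). The laminin chain Lama2 fell by 5.57 (SE 0.38, edgeR adjusted p = 0.000827), Fbn2 by 5.42, Mfap4 by 5.12, Thy1 by 5.02, Pdgfrb by 4.79 and Fap by 4.29. Other large falls were those of the potassium channel genes Abcc9 (−5.49) and Kcnma1 (−5.07), of the prostaglandin receptor gene Ptger3 (−5.16) and of the lectin gene Reg3b (−5.95; SE 0.87, edgeR adjusted p = 0.0106). Ptger3 did not pass without mouse 2542, 2689 or 2691 (−4.95 to −4.99). Of 13 acinar markers 4 fell (9 adjusted over the list alone), with a median of −3.69 (camera adjusted p = 0.000228, and adjusted p = 0.541 with an estimated correlation). The 4 were the digestive enzymes Prss2 (−6.98), Ctrb1 (−6.16; 9.73 ± 12.4 against 1199 ± 1588 CPM), Cpb1 (−5.64) and Cpa1 (−5.21). The acinar list mean was lower in 4 mice, by 3.09 to 6.21, and higher by 0.38 in mouse 0784 and by 0.20 in mouse 2689, whose cells were also gated as EpCAM-negative. Ctrb1 and Cpb1 did not pass without mouse 2317, 2518, 2542, 2689 or 2691 (Ctrb1 −5.77 to −6.34, Cpb1 −4.83 to −5.62), nor Cpa1 without 2317, 2518, 2542 or 2691 (−4.42 to −5.03), while Prss2 passed without each mouse.

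Several other programmes were lower in GFP-positive cells. The 29 cell cycle genes all had negative changes, with a median of −1.05 (camera adjusted p = 5.4e-06, and adjusted p = 0.541 with an estimated correlation), but none passed the test alone. Among them were Mki67, a marker of cycling cells (−1.76, edgeR adjusted p = 0.0804, lower in 5 of 6 mice), Ccnb2 (−2.07) and Tyms (−1.03), and these 3 passed without mouse 0784 (−2.22, −2.56 and −1.30) and by DESeq2 (adjusted p = 0.000462, 0.000185 and 0.00122). The mesenchymal list had 4 falls in 24 genes, Sparc, Tagln, Fbn1 and Lox, and a median of −0.60 (camera adjusted p = 0.000847, and adjusted p = 0.541 with an estimated correlation). Without mouse 2518 Tagln (−2.64), Fbn1 (−3.29) and Lox (−2.76) did not pass, nor Tagln (−2.43) and Lox (−2.48) without 2542. The same held for all 4 without 2689 (Sparc −3.34, Tagln −2.44, Fbn1 −3.45, Lox −2.64) and for Tagln (−2.91) and Lox (−3.20) without 2691. The matrix list had 2 rises and 6 falls in 25 genes with a median of −0.69 (camera adjusted p = 0.00535, and adjusted p = 0.541 with an estimated correlation). Its rises, the collagen hydroxylases P4ha1 (1.84) and P4ha2 (1.55), are also members of the hypoxia list, and 3 of its genes, Col1a1, Col1a2 and Col3a1, are also fibroblast markers. Interferon and antigen presentation genes had 2 falls in 24, Tapbp and Gbp3, and a median of −0.71 (camera adjusted p = 0.00133, and adjusted p = 0.329 with an estimated correlation). Gbp3 did not pass without mouse 2317, 2518, 2542, 2689 or 2691 (−1.58 to −1.99), nor Tapbp without 2691 (−0.53). Oxidative phosphorylation had 1 fall in 26, Ndufa4, and a median of −0.25 (camera adjusted p = 0.000113, and adjusted p = 0.541 with an estimated correlation). Markers of 4 more cell types moved the same way. The medians were −2.18 for 8 hepatocyte, −1.26 for 11 endothelial, −0.61 for 15 macrophage and −1.61 for 5 muscle or adipocyte markers (camera adjusted p = 0.000847, 0.000847, 0.0462 and 0.0346). With an estimated correlation their adjusted p were 0.341, 0.341, 0.724 and 0.329.

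A smaller set of signalling programmes was higher. Immediate early and dissociation stress genes had 4 rises in 19, Klf6, Dnajb1, Fos and Jund, and a median of 0.46 (camera adjusted p = 0.00297, and adjusted p = 0.541 with an estimated correlation). Dnajb1, Fos and Jund did not pass without mouse 2317, 2518, 2542, 2689 or 2691 (Dnajb1 0.85 to 1.10, Fos 0.61 to 0.80, Jund 0.59 to 0.83). MAPK output had 4 rises in 20 and a median of 0.28 (camera adjusted p = 0.00649, and adjusted p = 0.314 with an estimated correlation). They were the growth factor Hbegf (0.79), the feedback genes Dusp4 (0.80) and Spred2 (0.50), and the survival gene Ier3. Hbegf (0.78) and Dusp4 (0.80) did not pass without mouse 2542, nor Spred2 without 2317, 2518, 2542, 2689 or 2691 (0.46 to 0.54). TGF-β targets had 5 rises in 15, among them Id2 (1.51), Bhlhe40 (1.38) and Smad7 (1.03), and a median of 0.25 (camera adjusted p = 0.0269, and adjusted p = 0.524 with an estimated correlation). Targets of the microRNA let-7 and oncofetal genes had 2 rises in 13, the RNA-binding protein Igf2bp2 (1.13) and the zinc finger gene Plag1 (1.79), and a median of 0.32 (camera adjusted p = 0.0358, and adjusted p = 0.329 with an estimated correlation). Smad7 did not pass without 2542 (0.96), nor Plag1 without 2518, 2542 or 2691 (1.64 to 1.94). Mir147, which rose by 3.11 log2 units, lies inside another gene, so its counts are uncertain. 12 lists did not pass the camera threshold. Their medians were 0.06 for epithelial junctions and keratins, −0.49 for duct and gastric-type differentiation, 0.09 for basal or squamous epithelium, −0.46 for NF-kB targets and 0.32 for p53 targets. They were 0.16 for the unfolded protein response, −0.23 for cholesterol synthesis, −0.41 for neutrophil, −1.52 for B and plasma cell, 0.01 for erythroid, −0.22 for lung epithelium and −1.07 for mesothelium markers. Among those 12 lists the p53 target Cdkn1a, a cell cycle inhibitor, rose by 1.71 (edgeR adjusted p = 0.00689) and the chemokine gene Ccl2 fell by 3.29, a call that was lost without mouse 2542 (−3.12) or 2689 (−3.46). The median, mean and direction of the test differed in sign for p53 targets, erythroid and lung epithelium markers. T and NK cell and islet markers had too few measured members to be tested.

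In all, 798 genes were higher and 668 lower of 16804 tested (edgeR, mouse as block). By at least 2-fold, 175 were higher and 423 lower, and 1351 of the 1466 had the same sign in every pair. Without the block there were 117 and 220, DESeq2 called 1519 and 1815, and with the acinar list mean as a covariate, chosen after seeing the data, 112 and 25 were past the threshold. The 3 pairs whose column labels do not conflict gave 10 and 35, and reading the conflicting columns by their cross-reference gave 0 and 0 (432 at an unadjusted p under 0.05). Leaving out 1 mouse gave 1159 and 1211 genes without 0784, 514 and 485 without 2317, 374 and 268 without 2518, 183 and 137 without 2542, 241 and 162 without 2689, and 224 and 159 without 2691.

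**Figure D2:**
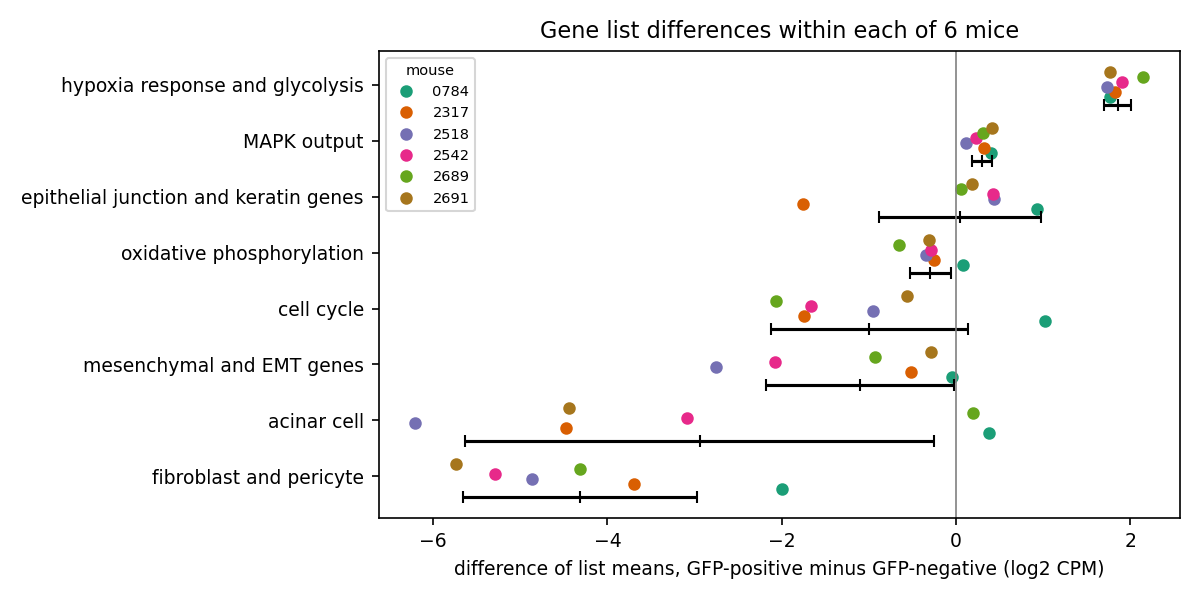
Difference of list means, GFP-positive minus GFP-negative (log2 CPM), for 8 gene lists in 6 mice; each point is 1 mouse and the bars are the mean and 1 SD. The hypoxia list lies between 1.73 and 2.15 in every mouse, and the fibroblast list between −5.74 and −2.00.

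The second question was how metastases differ from primary tumours of the same mice. Genes of the normal exocrine and endocrine pancreas were lower in the 13 solid metastases than in the 9 primary tumours. The 13 acinar markers had a median log2 change of −3.33 (camera adjusted p = 5.1e-27, and adjusted p = 0.00939 with an estimated correlation); 1 fell, and 8 fell adjusted over the list alone. The 4 islet markers had a median of −2.30 (camera adjusted p = 1.3e-09, and adjusted p = 0.0121 with an estimated correlation). The acinar and islet list means were lower in the metastases of 8 of 8 mice. Of 17142 genes, 0 were higher and 6 lower in metastases (edgeR, mouse as block), with 383 at an unadjusted p under 0.05, where 857 are expected by chance. Of these 6 only Reg2, a secreted lectin of the pancreas (chromosome 6, 78395623 to 78408106), met the rule for large changes. It fell by 7.68 on the log2 scale (SE 1.23, edgeR adjusted p = 0.0499), from 21 ± 17.3 CPM (SD, n = 9) to 1.2 ± 4.09 (n = 13), and was lower in 8 of 8 mice. Cpb1, an acinar carboxypeptidase, fell by 5.91 (SE 0.94, edgeR adjusted p = 0.0499), from 8.49 ± 9.12 to 0.2 ± 0.454 CPM. The other 4, named after their values were seen, were Clps (−3.30), Zg16 (−5.29), Sycn (−4.07) and the gene model 2210010C04Rik, the first 3 being genes of acinar secretion. Sst, which encodes the islet hormone somatostatin, differed by −5.04 (edgeR adjusted p = 0.114).

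The changes of Hmga2 and Prdm1 between metastases and primary tumours of the same mice did not pass the test and were about as large as their SE. Hmga2 was 157 ± 87.0 CPM in metastases and 173 ± 78.2 in primary tumours (log2 change −0.42, SE 0.41, edgeR adjusted p = 1), lower in 4 of 8 mice. Much of the Hmga2 change rests on single libraries, since it was −0.11 without mouse 0758 and −0.30 without the lung library. Prdm1 was 10.1 ± 6.27 and 11.8 ± 6.64 CPM (log2 change −0.35, SE 0.36, edgeR adjusted p = 1), lower in 7 of 8 mice. In the primary tumours of mice 0758, 2254, 2255, 2492, 2518, 2542, 2691, 2752 and 2854, Hmga2 stood at 298, 179, 80.7, 267, 61.8, 203, 120, 165 and 177 CPM and Prdm1 at 3.67, 23.9, 9.19, 6.21, 6.9, 11.1, 11.2, 20.2 and 13.1. In the lymph node metastases of 0758, 2255, 2492, 2542, 2691 and 2854, Hmga2 was at 14.9, 105, 291, 188, 119 and 104 CPM and Prdm1 at 9.42, 2.86, 4.25, 7.28, 5.42 and 16.1. In the liver metastases of 2254, 2542, 2691 and 2752, Hmga2 was at 208, 176, 217 and 133 CPM and Prdm1 at 21.5, 15.2, 7.86 and 14.7. In the splenic, thoracic and lung metastases Hmga2 was at 298, 118 and 35.7 CPM and Prdm1 at 17.3, 4.18 and 3.89, and in the peritoneal library they were at 64.8 and 1.86.

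9 more lists passed the camera threshold in this comparison, without a gene past its own, and none of the 9 passed with an estimated correlation. The medians were −0.28 for duct and gastric-type differentiation, −0.24 for the epithelial list, −0.18 for immediate early genes and −0.27 for macrophage markers. They were 0.20 for the cell cycle, with 29 of 29 genes positive, 0.19 for the unfolded protein response, 0.13 for cholesterol synthesis, 0.07 for oxidative phosphorylation and 0.59 for muscle or adipocyte markers. With an estimated correlation the adjusted p of these 9, in the same order, were 0.489, 0.514, 0.514, 0.489, 0.802, 0.352, 0.514, 0.516 and 0.273. The hypoxia list had a median of 0.05 (camera adjusted p = 0.993), and without the block it turned direction and passed (adjusted p = 0.019). The other lists not past the threshold had medians from −0.22 to 0.78. Median, mean and direction differed in sign for the hypoxia, B and plasma cell and lung epithelium lists. The lung metastasis library, 1 of the 13, had the surfactant gene Sftpc at 58400 CPM, so that its share of pancreatic cancer cells is uncertain. Without it, an alternative chosen after seeing the data, 5 genes were lower and 753 had an unadjusted p under 0.05. The 6 lower genes became 2 without the block, 30 by DESeq2 (with 1 higher), 3 with RLE size factors, 0 with the stricter filter, 1 with lymph node and liver metastases alone, 0 with metastases summed per mouse, and 0 by either treatment of the conflicting columns. They became 1 without mouse 0758, 2255, 2542 or 2752, 2 without 2254, 2518 or 2691, 3 without 2492 and 13 without 2854. Reg2 (−7.22 to −8.39) and Cpb1 (−5.37 to −6.39) did not pass without any 1 mouse other than 2854, Cpa1 (−7.26) and Ctrb1 (−8.15) passed without 2854, and Clps passed without each mouse. Zg16 did not pass without 0758, 2255, 2542, 2691 or 2752 (−4.82 to −5.72), Sycn passed only without 2691 or 2854, and 2210010C04Rik only without 2492 or 2854.

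In lymph node metastases, genes of the cell cycle and of cholesterol synthesis were slightly higher than in primary tumours and acinar genes were lower, with no gene past the threshold. The cell cycle list had 29 of 29 positive changes (7 rose adjusted over the list alone) and a median of 0.37 (camera adjusted p = 1.24e-13, and adjusted p = 0.295 with an estimated correlation). Mki67 stood at 139 ± 32.1 CPM (SD, n = 6) against 106 ± 50 in primary tumours (n = 9), a log2 difference of 0.48 (SE 0.12, edgeR adjusted p = 0.618, DESeq2 adjusted p = 0.0485), higher in 6 of 6 mice. The checkpoint kinase Bub1 (0.50), Cdc20 (0.49) and Aurka (0.48) were also higher in 6 of 6. Cholesterol synthesis had 18 of 18 positive changes and a median of 0.29 (camera adjusted p = 4.49e-09, and adjusted p = 0.295 with an estimated correlation), as in Fdps (0.57), Ldlr (0.42) and Lss (0.42). The 15 acinar markers had a median of −4.16, also with the gene at 0 in every lymph node library set to its bound (9 fell adjusted over the list alone; camera adjusted p = 2.26e-13, and adjusted p = 0.295 with an estimated correlation). The acinar list mean was lower in 5 of 6 mice and higher by 0.38 in mouse 2854. The 7 muscle or adipocyte markers had a median of 0.84 (camera adjusted p = 0.00045, and adjusted p = 0.197 with an estimated correlation), with the adipocyte genes Cfd at 2.34 and Fabp4 at 1.29. Immediate early genes had a median of −0.28 and islet markers one of −2.17 (camera adjusted p = 6.31e-05 and 0.000119, and adjusted p = 0.295 for both with an estimated correlation). 7 further lists passed camera, with medians from −0.95 for hepatocyte markers to 0.40 for fibroblast markers, and adjusted p of 0.295 or 0.586 with an estimated correlation. Hmga2 differed by −0.59 (edgeR adjusted p = 0.83), or by −0.12 without mouse 0758, and Prdm1 by −0.43 (0.814). Of 17498 genes 0 were higher and 0 lower by edgeR, with 1214 at an unadjusted p under 0.05 (875 expected by chance), and DESeq2 called 22 and 78.

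Liver metastases carried more transcripts of plasma proteins that hepatocytes secrete. All 16 measured hepatocyte markers had positive changes against primary tumours (9 rose adjusted over the list alone), with a median of 3.31 (camera adjusted p = 2.82e-20, and adjusted p = 0.00948 with an estimated correlation). The fibrinogen gene Fgb stood at 21.7 ± 18.3 CPM (SD, n = 4) against 0.21 ± 0.317 in primary tumours (n = 9), a log2 difference of 7.57 (SE 0.92, edgeR adjusted p = 0.0576). Alb, which encodes albumin, stood at 117 ± 114 against 1.31 ± 1.51 CPM (6.87, edgeR adjusted p = 0.134), Fga differed by 5.32 and Ahsg stood at 10.6 ± 8.57 against 0.362 ± 0.36 CPM, and all 4 were higher in 4 of 4 mice. Hypoxia genes had 33 of 37 positive changes and a median of 0.36 (camera adjusted p = 1.72e-08, and adjusted p = 0.503 with an estimated correlation), for example Gbe1 (0.94), P4ha1 (0.78) and Kdm3a (0.34). The hypoxia list mean was higher in 3 of 4 mice, with differences from −0.04 to 0.53. The unfolded protein response had a median of 0.27 (camera adjusted p = 0.00011, and adjusted p = 0.497 with an estimated correlation). Acinar markers had a median of −3.13 and islet markers of −6.25, or −5.29 with genes at 0 in every liver library set to their bound (camera adjusted p = 9.87e-11 and 1.45e-08). With an estimated correlation these were adjusted p = 0.433 and 0.35. 5 further lists passed camera, with medians from −0.59 for macrophage to 1.59 for T and NK cell markers and adjusted p of 0.497 to 0.758 with an estimated correlation. Hmga2 differed by 0.01 and Prdm1 by −0.03. Of 17858 genes 0 were higher and 0 lower by edgeR, with 1394 at an unadjusted p under 0.05 (893 expected by chance). DESeq2 called 66 and 85, the fit without the block 5 and 0, the fit without a filter 1 and 0, leaving out mouse 2492 gave 2 and 0, and leaving out 2691 gave 1 and 3, the 1 higher gene being Fgb (8.96).

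Set against each other, liver metastases exceeded lymph node metastases in hepatocyte genes. The hypoxia list was higher too, but it passed camera only at the preset correlation and not with unconflicted columns. In mice 2542 and 2691 the hepatocyte list mean was higher in liver by 4.96 and 3.94 log2 units and the hypoxia list mean by 0.65 and 0.71. The cell cycle list mean differed by −0.72 in 2542 and by 0.36 in 2691, and the cholesterol synthesis mean by 0.12 and −0.89. The columns of both sites have conflicting labels in both mice. With unconflicted columns, where no mouse gives both sites, the hepatocyte and cell cycle lists passed camera in the same direction (adjusted p = 6.63e-12 and 1.24e-09), the hypoxia list did not (adjusted p = 0.384), and in lymph node against primary tumour the hypoxia list turned direction and passed (adjusted p = 0.00254). Only these 2 mice gave both sites, so the genes named here were chosen after their values were seen. Of 17205 genes, 4 were higher in liver metastases, Fgb (21.7 ± 18.4 against 0.052 ± 0.0818 CPM, log2 difference 9.92, SE 1.08, edgeR adjusted p = 0.0156), Fga (8.38), the methyltransferase gene Bhmt (9.11; SE 0.92, edgeR adjusted p = 0.0151) and the kininogen gene Kng1 (7.80). The matrix gene Fmod (−5.51, edgeR adjusted p = 0.0478) and the ribonuclease gene Rnase4 (−1.59, edgeR adjusted p = 0.0405) were lower. Of 16 hepatocyte markers 15 were positive and 2 rose (12 adjusted over the list alone), with a median of 4.19 (camera adjusted p = 1.84e-16, and adjusted p = 0.0183 with an estimated correlation). The hypoxia list had 34 of 37 positive and a median of 0.35, and the cell cycle list 28 of 29 negative and a median of −0.42 (camera adjusted p = 1.03e-06 for both, and adjusted p = 0.439 for both with an estimated correlation). Cholesterol synthesis had a median of −0.39 (camera adjusted p = 2.02e-05, and adjusted p = 0.439 with an estimated correlation), and passed with unconflicted columns (adjusted p = 0.0126) but not without the block (adjusted p = 0.0662). 10 further lists passed camera, with medians from −1.54 for muscle or adipocyte to 1.23 for T and NK cell markers and adjusted p of 0.355 to 0.593 with an estimated correlation. The 4 and 2 genes became 3 and 0 without the block, 189 and 126 by DESeq2, 0 and 0 with the stricter filter, and 0 and 0 by either treatment of the conflicting columns. They became 0 and 0 without mouse 2255 or 2542, 1 and 0 without 0758, 4 and 0 without 2492, 2 and 4 without 2691, 3 and 0 without 2752, 3 and 1 without 2254, and 10 and 2 without 2854.

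**Figure D3:**
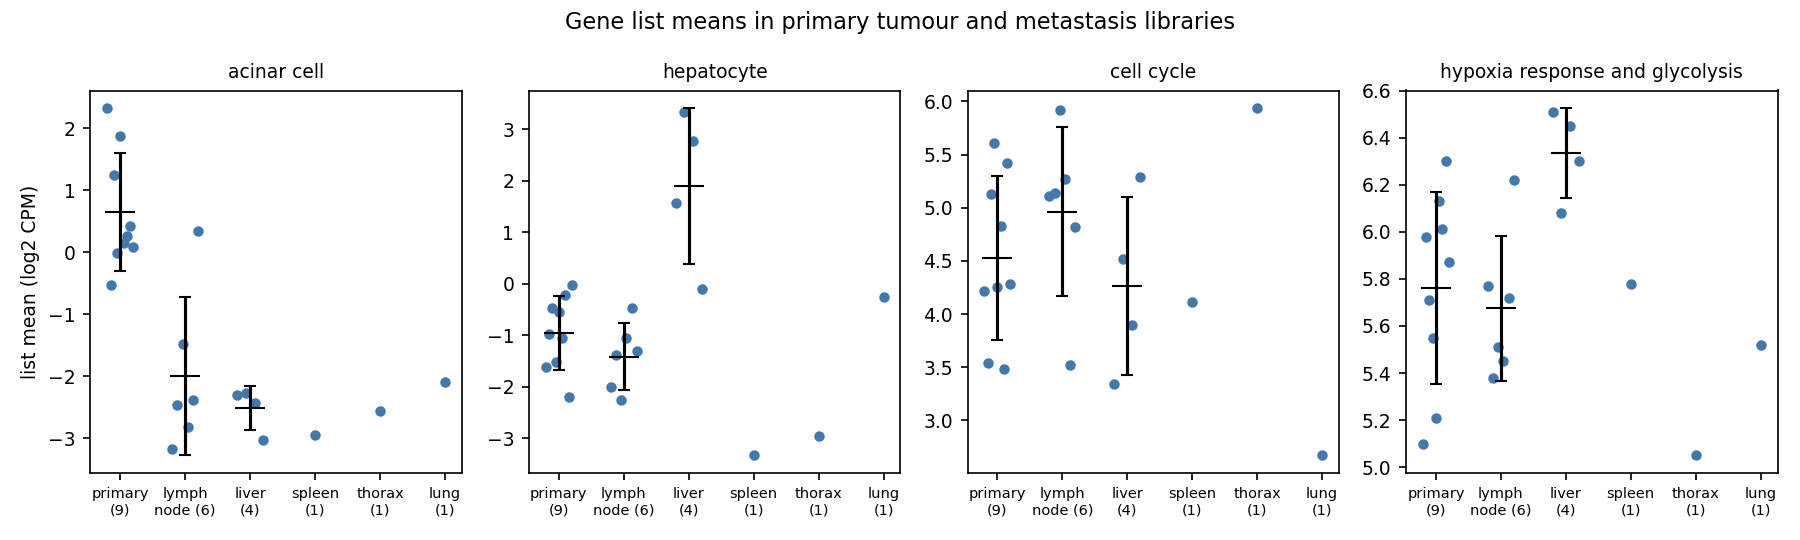
List means (log2 CPM) of acinar, hepatocyte, cell cycle and hypoxia genes in each library by site; each point is 1 library and the bars are the mean and 1 SD where a site has more than 1 library. The hepatocyte list is highest in the liver metastases of mice 2254, 2542 and 2691 (1.57, 3.34 and 2.76), and the acinar list lies between −0.52 and 2.33 in primary tumours.

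The next question was whether the genes that mark GFP-positive cells are also higher in metastases. Neither the higher nor the lower genes passed the test as a set. The 798 genes higher in GFP-positive cells had a median log2 change of −0.03 in metastases, with 323 positive (camera adjusted p = 0.133, and adjusted p = 0.921 with an estimated correlation). The 665 lower genes measured there had a median of 0.06, with 404 positive (camera adjusted p = 0.699). Among them 4 were past the threshold, all lower in metastases. Across 16550 genes, which are not independent replicates, the changes in the 2 comparisons had Pearson r = 0.11 and Spearman rho = −0.09. The comparisons share no library but 3 mice, and without those mice the medians were −0.02 and 0.05.

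Hmga2 was then compared between primary tumours of mice with and without the reporter allele. It stood at 128 ± 71 CPM in 3 KPC-colors and 194 ± 77.9 CPM in 6 KPCT tumours (SD). The difference of −0.65 log2 units did not pass an exact two-sided permutation test (p = 0.262, where the smallest p the 84 splits allow is 0.0119).

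Across the 9 whole primary tumours Prdm1 followed the hypoxia list, and the 2 relations of Hmga2 did not pass the test. Prdm1 and the hypoxia list mean had Pearson r = 0.86 (exact permutation p = 0.00341, adjusted p = 0.0102 over 3 relations) and Spearman rho = 0.78 (exact permutation p = 0.0172, adjusted p = 0.0516). Without the 2 tumours farthest from the median r was 0.86, and without mouse 0758 it was 0.76 with an adjusted permutation p of 0.081. Within the 6 KPCT tumours, a subset chosen after seeing the data, r was 0.94 (exact permutation p = 0.00556), and 3 KPC-colors tumours are too few for a value. Hmga2 and Prdm1 had r = −0.13 (exact permutation p = 0.742, adjusted p = 0.873) and rho = −0.25 (exact permutation p = 0.521). Hmga2 and the hypoxia list had r = 0.06 (exact permutation p = 0.873) and rho = −0.13 (exact permutation p = 0.744). Without the 2 tumours farthest from the median these 2 values of r were −0.71 and −0.77, and within KPCT tumours −0.42 and −0.45. Without mouse 0758 they were positive, at 0.27 and 0.5.

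**Figure D4:**
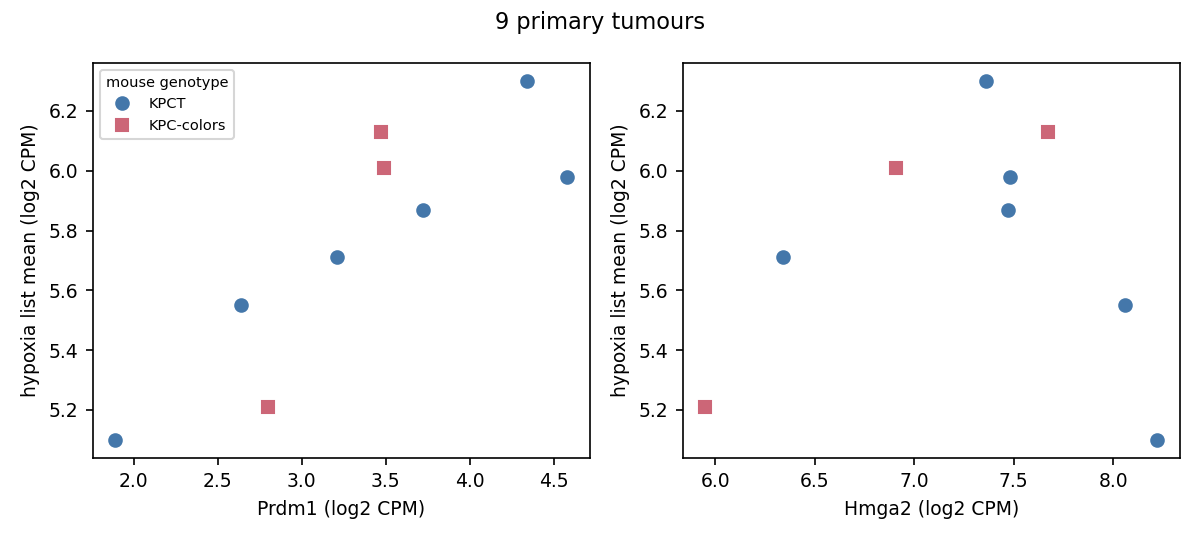
Prdm1 and Hmga2 (log2 CPM) against the hypoxia list mean (log2 CPM) in 9 primary tumours; each point is 1 mouse, with KPCT and KPC-colors marked. Prdm1 rises with the list (r = 0.86) and Hmga2 shows no such relation (r = 0.06).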

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

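The tests of the hypoxia pattern and of the liver and pancreas patterns were chosen after the results were seen, while the member correlations and the splits of the samples were set before.

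Hypoxia and glycolysis genes were higher in the GFP-positive library of 6 of 6 mice. Fewer non-epithelial cells in those libraries would raise every transcript of the cancer cells alike. But the epithelial list had a median log2 change of 0.06 (SD of its members 0.36) against 1.83 for the hypoxia list. Its list mean differed by −1.76 to 0.93 in the 6 mice. In mice 2518, 2542 and 2691 the epithelial gene Epcam stood at 430 to 803 CPM in both libraries. In these mice a loss of non-epithelial cells alone does not account for the hypoxia rise. In mice 0784, 2317 and 2689, the last gated as EpCAM-negative, Epcam was at 5.4 to 65.8 CPM. The list may not gauge the share of cancer cells there, so it cannot decide the question for them. The epithelial list cannot test a loss of other epithelial cells, such as acinar cells, which may carry the same genes. A difference in depth does not account for the hypoxia rise, since the list difference was still 1.77 or more in mice 2689 and 2691, where the GFP-positive library had the lower total count. Conflicting column labels do not account for it either, since the 3 pairs without them differed by at least 1.73. Read by column name, the pairs of mice 0784, 2542 and 2691 differed by 1.77, 1.9 and 1.77, within the range of the pairs without conflict. For these 3 pairs the values argue against the cross-reference reading. That GFP-positive cells sit in, or respond to, low oxygen may be a biological reading, which stays an untested hypothesis and says nothing of Hmga2 itself, whose change of 0.99 did not pass (edgeR adjusted p = 0.055).

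Fibroblast and acinar genes were lower in GFP-positive libraries. Normal acinar cells in the GFP-negative sort would carry Tomato and pass the gate, and the acinar members moved together over the 6 pairs, with a median correlation of 0.78 (78 of 78 pairs of members positive). Fibroblast members had a median correlation of 0.61 (76 of 78 positive), although the Tomato gate should remove fibroblasts. Both lie between the bounds of 0.3 and 0.8 set for these tests, so that admixed cells and a change in the cancer cells cannot be told apart for either list. Ctrb1 at 1210 and Col1a1 at 988 CPM on the common scale were the most abundant members of the lists in GFP-negative libraries, and mesenchymal cancer cells or doublets may be a source as well, which was not tested.

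Hepatocyte genes were higher in liver metastases, and acinar and islet genes were lower in metastases than in primary tumours. For the first part, RNA of hepatocytes and cancer cells that switch on plasma protein genes in the liver cannot be told apart, since both predict a list that is not higher in lymph node metastases (median −0.95). The Tomato gate should remove hepatocytes, and Alb reached 248 CPM in liver libraries while the hepatocyte genes Cyp2e1, Cyp3a11, Mup3 and Mup20 stayed at or under 2.15 CPM. For the second part, normal pancreas cells in the primary tumour libraries, which the Tomato gate would keep, stay open, since the islet median of −2.30 is part of the pattern and does not test them. The site of growth stays open as a biological cause and was not tested.

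Other splits of the same libraries were counted for each comparison, with 100 splits each. For GFP, 1 of 100 splits, the real one, gave 1466 genes or more and the highest other gave 72. Of the 32 splits that part all 6 pairs the highest other also gave 72, and the 68 that part fewer gave at most 9. For any metastasis, 1 of 100 gave as many as the real 6 and the highest other gave 2, and the 50 splits that part as many mice gave 0 apart from the real one. For liver against lymph node, 1 of 100 gave as many as the real 6 and the highest other gave 2. No other split reached the real count in these 3 comparisons. So few splits cannot exclude chance, since the smallest share they allow is 1 of 100, or 1 of 32 within the GFP pairs. The 6 of liver against lymph node are weak, as they became 0 with unconflicted columns and by the cross-reference. They were also 0 without mouse 2255 or 2542. The stricter filter gave 0 too, but it asks for 1 CPM in 50% of the libraries. It may remove genes present mainly in liver libraries, such as Fgb, before any test, so its 0 does not bear on them. The 6 of any metastasis stay weak, since 0 were called with unconflicted columns, by the cross-reference and with counts summed per mouse. The stricter filter gave 0 as well, but it may remove genes that are scarce in metastases before any test. At an unadjusted p under 0.05 there were 383 genes, where 857 are expected by chance. Without the lung library there were 753, so much of that shortfall rests on 1 library and says little about the 6. For lymph node and for liver against primary tumour the real count was 0, which 100 of 100 splits reach whatever the data, so the count says nothing about chance. The highest other splits gave 154 and 1 genes. The 154 came from 1 split of the lymph node comparison, where 97 of 100 gave 0. That split parted only 1 mouse, so its contrast has little support within mice. Other splits that parted 1 mouse gave 0, and the cause of the 154 was not identified.

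The same splits were counted for the number of lists past camera at the preset correlation. As many as the real 16 lists came from 5 of 100 splits for GFP (highest other 17), as many as 11 from 10 for any metastasis (highest other 13), and as many as 10 from 32 for liver against primary tumour (highest other 15). Over all 100 splits chance is not excluded for the counts of any metastasis and of liver against primary tumour. For GFP the 100 splits cannot decide. With mouse as a block, splits that part fewer pairs rest on the parted pairs alone and may repeat or mirror the real difference. As many as the real 13 came from 2 of 100 splits for lymph node (highest other 13) and as many as 14 from 3 for liver against lymph node (highest other 14). For GFP a hypoxia median as far from 0 as 1.83 came from 7 of 100 splits, of which all but the real one part fewer pairs. Of the 32 splits that part all 6 pairs, the real one alone gave 16 lists or a median as far, and the others gave at most 15 lists and 1.39. For liver against lymph node, a hypoxia median as far from 0 as the real one came from 15 of the 38 splits that part as many mice, so chance is not excluded for the hypoxia difference between the sites. For liver against primary tumour it came from 20 of 100 splits, and from 3 of the 16 that part as many mice, so chance is not excluded there either.

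A few single libraries stood far from their group; 50 groups of values were tested, 3 had such a library, and chance gives 5% of groups. Hmga2 was at 3.91 log2 CPM in the lymph node metastasis of mouse 0758, against 6.70 to 8.19 in the other 5 lymph node libraries. The islet list mean was −2.86 in the lymph node metastasis of mouse 2854, against −4.11 to −3.81 in the others. The cell cycle list mean was 5.04 in the GFP-positive library of mouse 0784, against 3.09 to 3.55 in the other GFP-positive libraries.

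The test of liver against lymph node metastases called 6 genes as differing between the sites. The log2 differences of these genes were 9.92 for Fgb, 9.11 for Bhmt, 8.38 for Fga, 7.80 for Kng1, −1.59 for Rnase4 and −5.51 for Fmod. Only mice 2542 and 2691 gave both sites. With the stricter filter, with unconflicted columns, by the cross-reference, or without mouse 2255 or 2542, 0 genes were called. Fmod turned to 0.91 by the cross-reference.

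The peritoneal library of mouse 0784, which entered the GFP comparison only under the cross-reference reading, stood apart in dividing cells. Mki67 was at 777 CPM, against 114 to 270 in the GFP-sorted libraries of the same mouse. Its cell cycle list mean was 6.55 (3.96 to 5.04 in those libraries) and its macrophage list mean 2.12 (−0.24 to 0.34).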

How the results depend on the processing

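The acinar covariate, the fit without the lung library and the KPCT subset were chosen after the data were seen. In the GFP comparison, the direction of the 69 called named genes was kept under DESeq2, RLE size factors, no filter, the stricter filter, the fit with no block, each mouse left out, unconflicted columns and the acinar covariate, as far as measured. Of the calls 54 of 69 were lost with unconflicted columns, 52 with the acinar covariate, 34 with no block, 32 without mouse 2542, 29 without 2691, 28 without 2689, 24 of 68 without 2518 and 14 of 68 without 2317. No filter lost 9, and RLE, the stricter filter and leaving out 0784 lost 2 each. Under the cross-reference reading none of 67 was called, 65 kept the direction, and Fos (−0.12) and Ovol1 (−0.29) turned. The counts of higher and lower genes were 1519 and 1815 under DESeq2, 117 and 220 with no block, 10 and 35 with unconflicted columns (3 pairs), 0 and 0 by the cross-reference, and 112 and 25 with the acinar covariate. Leaving out 1 mouse gave 183 to 1159 higher and 137 to 1211 lower. All 798 and 668 genes were among those DESeq2 called.

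For any metastasis DESeq2 gave 1 higher and 30 lower genes. The lower genes numbered 3 with RLE, 2 with no block, 1 with lymph node and liver metastases only, and 0 with the stricter filter, with unconflicted columns, by the cross-reference and with counts summed per mouse. They numbered 5 without the lung library and 1 to 13 with each mouse left out. For lymph node metastases DESeq2 gave 22 and 78, and every other alternative 0. For liver metastases DESeq2 gave 66 and 85, no filter 1 higher, no block 5 higher, and leaving out 1 mouse 0 to 2 higher and 0 to 3 lower. For liver against lymph node DESeq2 gave 189 and 126. The stricter filter, unconflicted columns and the cross-reference each gave 0 and 0 there, no block 3 and 0, and leaving out 1 mouse 0 to 10 higher and 0 to 4 lower, with Fmod turned to 0.91 by the cross-reference.

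Gene lists past camera numbered 16 for GFP, 11 for any metastasis, 13 for lymph node, 10 for liver and 14 for liver against lymph node. With an estimated correlation they were 1, 2, 0, 1 and 1, and by fry 9, 2, 0, 1 and 1. With no block they were 15, 10, 13, 7 and 8, and with unconflicted columns 15, 7, 12, 6 and 8. Lists that turned direction were hypoxia in any metastasis with no block (adjusted p = 0.019) and in lymph node with unconflicted columns (adjusted p = 0.00254). Epithelial genes turned in liver with no block (adjusted p = 0.478) and with unconflicted columns (adjusted p = 0.795), and in liver against lymph node with no block (adjusted p = 0.00117). In liver with unconflicted columns NF-kB (adjusted p = 0.866) and interferon genes (adjusted p = 0.00343) turned too. The block changed no other count of genes.

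Across primary tumours, leaving out 1 mouse gave r of −0.40 to 0.27 for Hmga2 with Prdm1, −0.42 to 0.50 for Hmga2 with hypoxia and 0.76 to 0.91 for Prdm1 with hypoxia. In KPCT tumours only, Hmga2 with hypoxia was −0.45. The medians of the GFP genes in metastasis and the difference of Hmga2 by genotype moved by less than the spread under their alternatives. Fewer samples enter the fits with unconflicted columns and with counts summed per mouse, and fewer genes under the stricter filter; the cause of the other changes was not tested. The unblocked fits differ from the blocked ones by leaving mouse differences in the spread. Depth limits genes with few counts, and 2-fold changes were called for 12 of 50 simulated genes in the GFP comparison. That number may be too low, since the simulated spread was estimated without the GFP term.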

Other observations

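The lung metastasis library of mouse 2854 carried an alveolar profile, so that it is uncertain whether it is a pancreatic metastasis, although it counts among the 13 of the any-metastasis comparison. Sftpc, a surfactant protein of alveolar type 2 cells, stood at 58400 CPM against 0.304 in the primary tumour of the same mouse, and its lung epithelium list mean was 9.23 log2 CPM against −2.54 to −0.35 in the 9 primary tumours. Pdx1, a pancreatic transcription factor, was at 1.08 CPM and Hmga2 at 35.7, against 6.27 and 177 in the primary tumour of that mouse. Its cell cycle list mean was 2.67 and its endothelial list mean 2.29, against 3.48 to 5.61 and −1.33 to 0.18 in the primary tumours. Xist, which female cells transcribe, was at 136 CPM beside 153 CPM of Y-linked transcripts, while the other libraries of this mouse had 0.816 and 7.26 CPM of Xist beside 234 and 201 CPM of Y-linked transcripts.

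The other sites with a single library also differed among themselves. The thoracic metastasis of mouse 2752 had Mki67 at 279 CPM, a hypoxia list mean of 5.05 against 6.30 in its primary tumour, and Prdm1 at 4.18 against 20.2 CPM. The splenic metastasis of mouse 2691 had a mesenchymal list mean of 6.23 against 4.58 in its primary tumour, an epithelial mean of 5.66 against 6.74, a duct and gastric-type mean of 0.55 against 5.48, and Hmga2 at 298 against 120 CPM. The peritoneal cells of mouse 0784 had a fibroblast list mean of −1.07 against 2.71 to 5.85 in the primary tumours, a mesenchymal mean of 2.78 against 4.28 to 6.09 and an immediate early mean of 3.61 against 5.41 to 6.58. Their oxidative phosphorylation mean was 6.97 against 6.22 to 6.64. With 1 library per site these differences have no replicate check.

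Y-linked transcripts and the epithelial gene Epcam varied within some mice. In mouse 2317 the GFP-negative library had 11.2 CPM of 4 Y-linked genes and Epcam at 65.8 CPM, and the GFP-positive library 0.078 and 5.4. In mouse 2492 the primary tumour had 12.3 CPM of the Y-linked genes and Epcam at 105 CPM, and the lymph node metastasis 0.937 and 1.99. Xist was at 31.7 CPM or more in every library of mice 0758, 2254, 2255, 2518 and 2542, and at 7.26 CPM or less in every library of the other mice except the lung library described above.

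Across all 35 libraries 2 gene models, AK018753 and GU332589, held 16.1 to 40.8% of the counts together, with a ratio between them of 1.004 to 1.017.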
